A study of Dictyostelium discoideum with 16 samples.

How the data were processed

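The series holds RNA sequencing of Dictyostelium discoideum amebae of strain AX3 from 4 genotypes, with 4 samples of each named in the labels (16 in all): WT, ttpA-C231S, ttpA-E236fsx and ttpA-Y242fsx. Cells grew in axenic medium to about 80% confluence, and libraries were made from 250 ng of RNA with 12 PCR cycles, per the labels. Whether the samples of a genotype are separately grown cultures is not stated in the sources used here, so the error between them covers whatever the samples of a group do not share. Counts of WT replicates 2 and 3 differed by a chi-square of 1.54 per degree of freedom, the nearest of all pairs to counting error alone. Other WT pairs gave 3.97 to 21.14 and pairs within a mutant 3.5 to 19.88, though depth also affects this measure. WT replicates 2 and 3 may thus be less independent than the others, which the p-values do not take into account. The labels give no batch, and each genotype may come from a single cell line, so that genotype and line cannot be separated.

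Per the submitters' processing notes, reads were handled with bcl2fastq, STAR 2.6.0c and featureCounts 1.5.1. The genome build, the annotation and the treatment of reads that match several places are not given in the sources used here. One deposited table holds raw read counts per gene, as whole numbers that differ in total between libraries, together with the length of each gene model, a column in another unit (base pairs). The lengths were multiples of 3 in 94.8% of genes and are called coding lengths here. The other deposited table holds normalized signal values: the ratio of raw to normalized value was a single constant per library for all genes above 0, so the authors divided each library by one size factor. The tool that set those factors is not given in the sources used here. Both tables list 12865 genes.

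The column names of both tables give WT, ttpA-C231S, ttpA-E236fsx and a further genotype that no label names. Its 4 columns were not used in any step. The ttpA-Y242fsx samples (4) have no column under that name and were not analysed here, although the names of both deposited tables list ttpA-Y242fsx. The match of columns to samples rests on the column names alone. Whether the columns of the further genotype bear a shifted name could not be settled, which would bear on no comparison made here unless other names were shifted too. All results rest on 12 libraries, 4 per group. Comparisons that had been planned over 16 libraries and 3 mutants were made over 12 libraries and 2 mutants, and ttpA-E236fsx against ttpA-C231S took the place of both frameshifts against ttpA-C231S. A planned search for an AU-rich motif downstream of genes was not run, as no genome sequence was used here. The ttpA gene was not found by its symbol, so its own level was not analysed here.

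Gene names are those of the deposited tables. Of the 12865 identifiers, 12728 matched a reference table of the AX4 assembly dicty_2.7, which was used for gene types, synonyms and the order of neighbouring genes. As the build behind the counts is not named, no positions are printed.

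Raw counts were fitted with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 9966 and removed 2899. TMM factors scaled the libraries, and a quasi-likelihood model with one mean per genotype over all 12 libraries gave 3 two-sided comparisons, each adjusted by the Benjamini-Hochberg method over all tested genes with a threshold of 0.05. Values per gene are TMM-scaled CPM (counts relative to library size), as mean ± SD of 4 libraries. Log2 fold changes are given ± an approximate SE, the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. For large changes with few counts in a group this can fall below the counting error, as for DDB_G0291223_RTE with 57 counts in ttpA-E236fsx. Total counts ran from 11557049 to 26233838 per library, and 1 TMM-scaled CPM was 11.2 reads in the shallowest library. Reads without molecular identifiers are not independent molecules, so count-based statements cover counting error only. Principal components were computed on log2 CPM with a prior count of 2.

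Named genes followed a rule. For each mutant against WT, it took the 15 higher and 10 lower genes with the largest absolute log2 fold change. They had to pass the threshold, have all 4 mutant libraries on one side of all 4 WT libraries, and have a mean of at least 5 CPM in the higher group. It also took the 10 higher and 10 lower genes called alike in both mutants, ranked by their smaller change, 5 genes per direction between the mutants, and up to 4 called members of each fixed list with a mean of at least 5 CPM over all libraries. The text names part of these, and says of a gene outside the rule that it was chosen after its values were seen.

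The gene lists, the comparisons with WT and their tests, the rule for named genes and the other settings tried were chosen before the data were examined. Of 27 fixed lists, 26 were tested with camera in limma 3.58.1 (preset inter-gene correlation 0.01, log2 CPM with a prior count of 2), adjusted over the 52 list tests of the 2 comparisons with WT, and over 26 between the mutants. The mitochondrially encoded genes had 0 members in the table. Each list was also tested with an estimated correlation and with fry. No camera call held with an estimated correlation. Counts of members are given from the adjustment over all tested genes and adjusted over the list alone. Some members were matched by symbol only, such as gapA among the glycolysis genes and atp1 among the metal ion transport genes, and these symbols may also name other genes. The prestalk list shares 3 of its 17 tested members with other lists, among them cprA and cprB with the pre-starvation list.

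Alternatives were DESeq2 size factors in edgeR, library size alone, no filter on counts, a DESeq2 1.42.0 Wald test, a fit of the compared groups alone, the replicate number as a block, limma on the deposited normalized values (log2 with a pseudocount of 1), and leaving out each library in turn. Replicate numbers did not pair the samples throughout. Over 12 pairs of libraries with one number, the correlation of their deviations from the group mean ran from -0.17 to 0.294. Of these pairs, 5 were closest to a library of their own number, and all 5 joined WT to a mutant. Pairs between the mutants ran from -0.084 to -0.03. Some pairing with WT thus stays open, and the block allows for it. The median log2 fold change of all tested genes was at most 0.016 with TMM factors and at most 0.083 with library size alone.

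The fits were tested on simulated data, negative binomial counts drawn from the WT means and the fitted spread with changes planted in one mutant. For ttpA-C231S against WT, 79% of 100 genes changed 1.5-fold and 86.9% of 99 genes changed 2-fold were called, with 7 false calls among 9802 genes. For ttpA-E236fsx against WT these were 70.4% of 98, 96.9% of 97, and 10 of 9809. Camera called a list with planted 1.3-fold changes and 0 of 25 unchanged lists. Genes were drawn independently of each other there, unlike in the data, where the estimated correlation was 0.605 for cytosolic ribosomal protein genes. The simulation therefore cannot check false calls for lists of correlated genes.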

Results

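RNA was sequenced from axenically growing amebae of the AX3 laboratory strain of Dictyostelium discoideum. The cells carried either the unaltered ttpA gene (WT) or an altered one, which the labels name ttpA-C231S, a substitution, and ttpA-E236fsx, a frameshift. The ttpA gene encodes a member of the tristetraprolin family, zinc finger proteins known to bind AU-rich stretches of mRNA 3' ends and to promote removal of the poly(A) tail and decay of the mRNA. Each of these 3 groups held 4 libraries. Total gene counts ran from 11557049 in WT replicate 2 to 26233838 in WT replicate 3, and the 10 most counted genes took 7.37% to 8.56% of a library. Of 12865 genes listed, 9966 had enough counts to be tested. The ttpA-Y242fsx group that the labels also name was not analysed here, and neither was the ttpA transcript itself.

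The 3 genotypes separated in the leading components of expression. The first component carried 51.1% of the variance, and its mean score was -29.1 ± 4.1 (SD, n = 4) in WT, 1.6 ± 1.7 in ttpA-C231S and 27.5 ± 2.0 in ttpA-E236fsx. On the next component, with 21.6% of the variance, ttpA-C231S stood at -20.3 ± 1.6, against 9.8 ± 7.3 in WT and 10.5 ± 6.4 in ttpA-E236fsx.

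**Figure D1:**
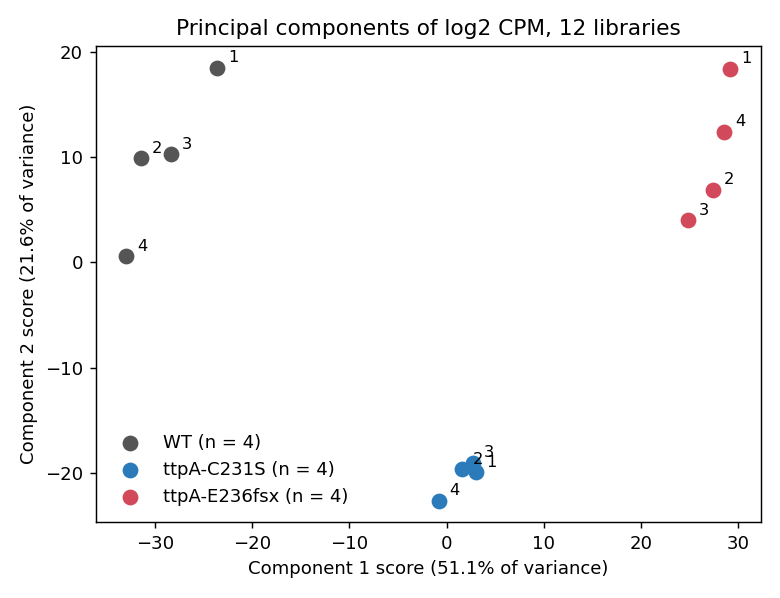
Scores of the 12 libraries on the first 2 principal components of log2 CPM (unitless scores; points are libraries, colours are genotypes, numbers are replicates). On the first component the ttpA-C231S libraries lie between the WT libraries (mean -29.1) and the ttpA-E236fsx libraries (mean 27.5).

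The comparison of ttpA-C231S with WT asks which transcripts differ in growing cells that carry the substitution. Among the leading changes, the transcript of sodC (DDB_G0282993), which encodes a superoxide dismutase, rose from 1015 ± 46.4 CPM (counts scaled by library size; SD, n = 4) in WT to 6134 ± 76.6 in ttpA-C231S, 6.04-fold (edgeR adjusted p = 1.65e-15). DD3-3 (DDB_G0283095) rose from 2348 ± 117 to 12512 ± 477 CPM, with a log2 fold change of 2.41 ± 0.044 (approximate SE, adjusted p = 5.63e-15). DDB_G0279951 rose furthest, from 0.817 ± 0.280 to 32.5 ± 3.26 CPM (log2 fold change 5.20 ± 0.202, adjusted p = 5.32e-11). Among the transcripts that fell, that of the cysteine protease gene cprF (DDB_G0279185) went from 466 ± 26.6 to 42.6 ± 4.06 CPM (log2 fold change -3.45 ± 0.0886, adjusted p = 3.72e-13). DDB_G0284277 fell from 146 ± 18.8 to 9.82 ± 0.484 CPM, 14.9 times lower (adjusted p = 1.78e-13). For each of these genes, all 4 ttpA-C231S libraries lay on one side of all 4 WT libraries, a condition set by the rule for leading genes.

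Across the 9966 tested genes, 1589 were higher and 1776 lower in ttpA-C231S than in WT at an adjusted p of 0.05, or 33.8% of them. The median absolute log2 fold change of the called genes was 0.31, and 200 of the higher and 170 of the lower genes changed at least 2-fold. The 4 libraries of the mutant did not overlap the 4 of WT in 32.9% of all tested genes, where chance gives 2.86% if libraries are independent. The balance of directions depends on the scaling: 47.2% of the called genes were higher with TMM factors and 60.2% with library size alone.

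Fixed gene lists moved in both directions in ttpA-C231S. Of 25 growth-phase cysteine proteases and lysosomal enzymes, 11 fell and 5 rose (12 and 6 adjusted over the list alone; camera adjusted p = 5.18e-04, adjusted p = 0.286 with an estimated correlation). Those that fell included tpp1F, a tripeptidyl peptidase gene (log2 fold change -1.83 ± 0.0514), cprE, a cysteine protease gene (-1.63 ± 0.0486), and ctsB, a cathepsin gene (-1.24 ± 0.0439). Of 17 genes that mark prestalk cells of the later multicellular stage, 11 rose and 2 fell (13 and 2 adjusted over the list alone; camera adjusted p = 0.00102, adjusted p = 0.172 with an estimated correlation). The largest rises among them were those of the developmental cysteine protease genes cprB (1.53 ± 0.136) and cprA (1.37 ± 0.0911), while dimB and carD, chosen after their values were seen, fell by 0.81 and 0.70 on the log2 scale. Of 32 DNA replication and cell cycle genes, 14 rose and 0 fell, which were also the counts adjusted over the list alone (camera adjusted p = 3.55e-05, adjusted p = 0.464 with an estimated correlation). Among these were the cyclin gene cycA (0.75 ± 0.0585), orcA of the origin recognition complex (0.37 ± 0.0621) and mcm4 of the replicative helicase (0.38 ± 0.0891). Of 33 polyketide synthase genes, 14 rose and 0 fell (15 and 0 adjusted over the list alone; camera adjusted p = 0.0014, adjusted p = 0.209 with an estimated correlation), among them pks28 (0.62 ± 0.129) and pks6 (0.50 ± 0.107).

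Of 79 cytosolic ribosomal protein genes, 70 fell and 0 rose (73 and 0 adjusted over the list alone), with a median log2 fold change of -0.193, as for rplP1 (-0.32 ± 0.0415) and rps28 (-0.32 ± 0.0398). The camera adjusted p was 2.65e-23, and the adjusted p was 0.341 with an estimated correlation. Of 9 subunit genes of the vacuolar proton pump, 7 fell and 0 rose (9 and 0 adjusted over the list alone; camera adjusted p = 0.00494, adjusted p = 0.459 with an estimated correlation). Of 31 heat shock and chaperone genes, 9 fell and 0 rose (11 and 0 adjusted over the list alone; camera adjusted p = 0.00609, adjusted p = 0.286 with an estimated correlation), among them the small heat shock gene hspI (-1.35 ± 0.233).

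Calls for 3 further lists lay near the threshold, and each was lost without any 1 of several libraries. Of 45 actin cytoskeleton genes, 15 fell, proA for profilin furthest (-0.52 ± 0.0357), and 1 rose (15 and 3 adjusted over the list alone; camera adjusted p = 0.0404, adjusted p = 0.691 with an estimated correlation). With library size alone 11 were lower and 5 higher. Without WT replicate 2, WT replicate 4, ttpA-C231S replicate 1 or ttpA-C231S replicate 2 the camera adjusted p was 0.0644, 0.14, 0.0673 and 0.0593. Of 29 cytochrome P450 genes, 8 rose and 1 fell (8 and 0 adjusted over the list alone; camera adjusted p = 0.0404, adjusted p = 0.423 with an estimated correlation), with cyp519E1 up by 1.18 ± 0.114. This call was lost without WT replicate 4, ttpA-C231S replicate 1 or ttpA-C231S replicate 2 (adjusted p = 0.0864, 0.0613 and 0.0593). Of 26 tricarboxylic acid cycle genes, 9 rose and 2 fell (10 and 2 adjusted over the list alone; camera adjusted p = 0.0348, adjusted p = 0.65 with an estimated correlation). With library size alone 14 were higher and 1 lower. Citrate synthase gene cshA rose by 0.38 ± 0.049 and isocitrate dehydrogenase gene idhC by 0.35 ± 0.0292. Both are members of the fixed list, and where in the cell their products act was not checked. The list's call was lost without WT replicate 3, ttpA-C231S replicate 3 or ttpA-C231S replicate 4 (adjusted p = 0.0511, 0.0578 and 0.0726).

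The comparison of ttpA-E236fsx with WT asks the same of the frameshift. The leading rise was that of the pseudogene DDB_G0280295_ps, from 4.57 ± 0.467 CPM (SD, n = 4) in WT to 174 ± 20.8 in ttpA-E236fsx, 38.8-fold (log2 fold change 5.28 ± 0.103, edgeR adjusted p = 5.45e-15). The neighbouring ponC1, ponC2, ponC3 and ponC4 genes, which are ponticulin-related, rose by log2 fold changes of 4.02 to 4.64, ponC4 from 3.39 ± 0.992 to 87.1 ± 20.2 CPM (adjusted p = 6.13e-11). Whether reads were shared between these genes was not tested. The ABC transporter genes abcA7 (log2 fold change 2.84 ± 0.184) and abcA8 (2.52 ± 0.172) rose as well. Expression of sodC was 5868 ± 300 CPM (log2 fold change 2.53 ± 0.0403, adjusted p = 2.30e-15) and that of DD3-3 was 14136 ± 697 CPM (2.59 ± 0.0443, adjusted p = 3.32e-15). The protease gene cprF fell to 13.1 ± 2.15 CPM, 35.4 times below WT (log2 fold change -5.15 ± 0.0995, adjusted p = 5.32e-15). DDB_G0284277 fell to 9.28 ± 1.05 CPM (-3.97 ± 0.0942, adjusted p = 6.27e-14).

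Of the 9966 tested genes, 2495 were higher and 2369 lower in ttpA-E236fsx than in WT, or 48.8%, with 481 and 166 changed at least 2-fold. The median absolute log2 fold change of the called genes was 0.36. The 4 and 4 libraries did not overlap in 42.7% of tested genes, against 2.86% by chance for independent libraries. Higher genes made up 51.3% of the called genes with TMM factors and 65.5% with library size alone.

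**Figure D2:**
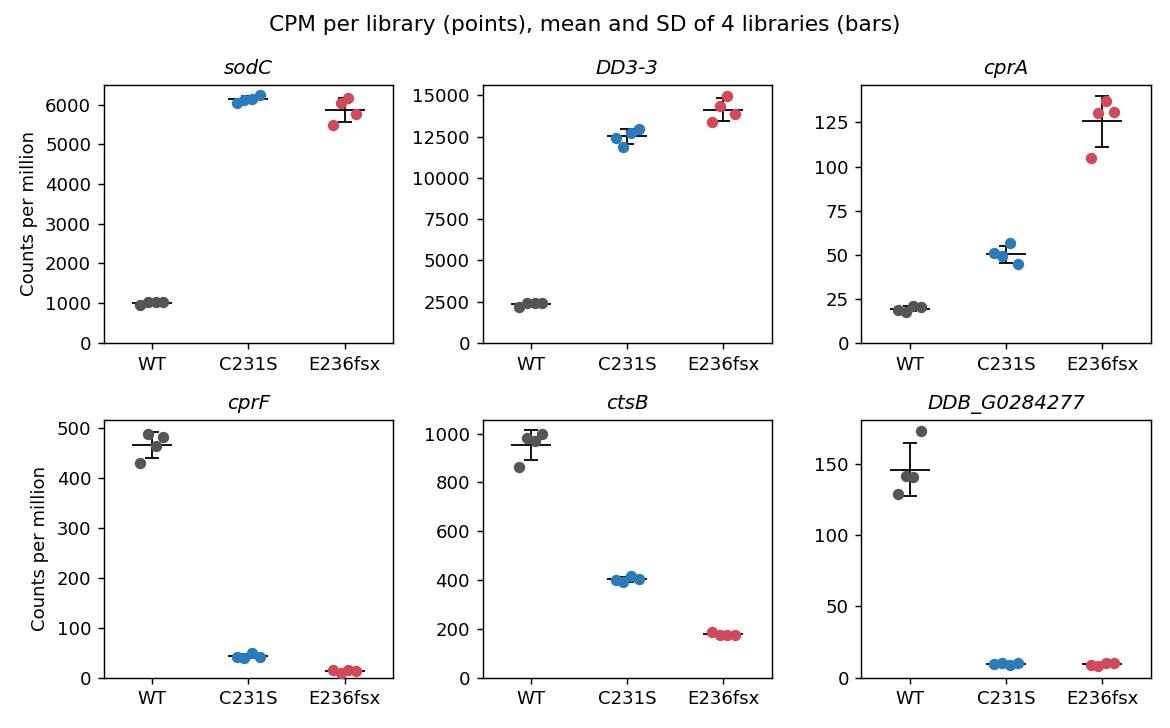
CPM of 6 genes in each library (points; 4 per genotype), with the mean and SD (bars), on linear axes that start at 0. For sodC, DD3-3 and DDB_G0284277 both mutants lie far from WT at similar levels, while for cprA, cprF and ctsB the ttpA-E236fsx libraries lie beyond those of ttpA-C231S.

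In ttpA-E236fsx, 16 of the 25 protease and lysosomal enzyme genes fell and 5 rose (17 and 5 adjusted over the list alone; camera adjusted p = 5.77e-06, adjusted p = 0.209 with an estimated correlation). Transcripts of tpp1F fell from 1752 ± 95.8 to 237 ± 12.2 CPM (log2 fold change -2.89 ± 0.0537), those of cprE by 2.61 and those of ctsB by 2.43 on the log2 scale. The members that rose included nagD (1.11) and tpp1D (1.48), named for a hexosaminidase and a tripeptidyl peptidase and chosen after their values were seen. Among prestalk genes, 14 of 17 rose and 1 fell (15 and 1 adjusted over the list alone; camera adjusted p = 1.35e-05, adjusted p = 0.104 with an estimated correlation), led by cprA (19.4 ± 1.53 to 126 ± 14.4 CPM), cprB (2.66 ± 0.130) and tagC (1.38 ± 0.069). Absolute levels of the prestalk list were low, with a median of 12.3 CPM over its members. Of 29 cytochrome P450 genes, 20 rose and 0 fell (21 and 0 adjusted over the list alone; camera adjusted p = 1.61e-04, adjusted p = 0.234 with an estimated correlation), cyp508A4 from 28.3 ± 1.19 to 149 ± 2.15 CPM.

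Ribosomal protein genes fell in 75 of 79 cases and rose in 0 (76 and 0 adjusted over the list alone), with a median log2 fold change of -0.36 and the largest falls in rplP1 (-0.71 ± 0.0417) and rps29 (-0.65 ± 0.0664). The camera adjusted p was 1.39e-29, and the adjusted p was 0.286 with an estimated correlation. All 9 vacuolar proton pump genes fell, also when adjusted over the list alone (camera adjusted p = 1.61e-04, adjusted p = 0.409 with an estimated correlation), vatG furthest (-0.40 ± 0.045). Of 45 actin cytoskeleton genes, 33 fell and 4 rose (33 and 6 adjusted over the list alone; camera adjusted p = 1.72e-07, adjusted p = 0.409 with an estimated correlation). They included corB for a coronin (-0.74 ± 0.0433) and the class I myosin genes myoB (-0.61 ± 0.0532) and myoC (-0.55 ± 0.0367). Of 31 heat shock and chaperone genes, 18 fell and 2 rose, the same counts as when adjusted over the list alone (camera adjusted p = 3.55e-05, adjusted p = 0.172 with an estimated correlation), with the endoplasmic reticulum chaperone gene grp94 at -0.70 ± 0.0677. Among 17 genes listed for mRNA deadenylation and decay, 9 fell and 1 rose, again also when adjusted over the list alone (camera adjusted p = 0.0106, adjusted p = 0.286 with an estimated correlation). A further 13 symbols of the planned list were not found, so the 17 cover only part of it. The helicase gene ddx6 (-0.44 ± 0.0366) and the exonuclease gene xrn1 (-0.31 ± 0.0421) were among those that fell. So was lsm8 (-0.46 ± 0.0807), a member by its symbol, whose role in decay was not checked.

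In ttpA-C231S, 5 mRNA decay genes fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.0579, and 0.0339 without ttpA-C231S replicate 4), with ddx6 at -0.23 ± 0.0365 and xrn1 at -0.37 ± 0.0421. In ttpA-E236fsx, 7 DNA replication and cell cycle genes rose and 0 fell (6 and 0 adjusted over the list alone; camera adjusted p = 0.13), with cycA at 0.28 ± 0.059. Without ttpA-E236fsx replicate 1 or WT replicate 4 that list's adjusted p was 0.00968 and 0.0306. Of the polyketide synthase genes, 13 rose and 5 fell in ttpA-E236fsx, also adjusted over the list alone (camera adjusted p = 0.409), with 16 higher and 2 lower by library size alone. Of the tricarboxylic acid cycle genes, 10 rose and 10 fell, by either adjustment (camera adjusted p = 0.781), but 13 were higher and 5 lower with library size alone, and the list's median of 0.01 moved between 0 and 0.079 with the scaling.

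**Figure D3:**
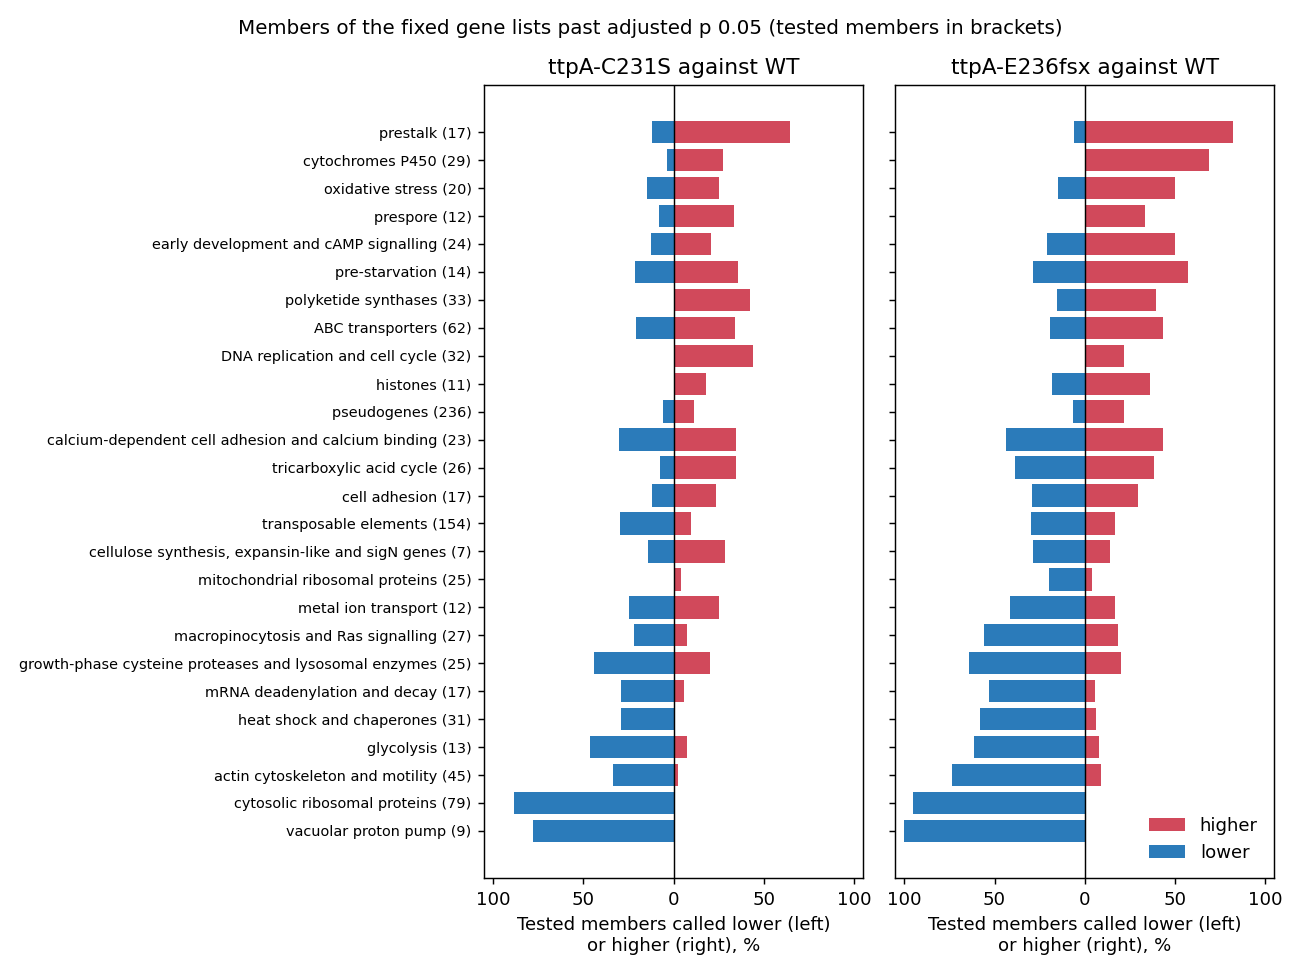
Percentage of the tested members of each fixed gene list that were lower (blue, left of 0) or higher (red, right of 0) than WT at an edgeR adjusted p of 0.05, for ttpA-C231S and ttpA-E236fsx, with 4 libraries per genotype. Ribosomal protein genes fell in 70 and 75 of 79 cases, and prestalk genes rose in 11 and 14 of 17.

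Comparing the calls of both mutants asks which transcripts changed alike. Both mutants shared the rises of sodC and DD3-3 given above, and those of uduB, from 217 ± 14.0 CPM (SD, n = 4) in WT to 690 ± 75.9 and 941 ± 132 in ttpA-C231S and ttpA-E236fsx, and of the calcium-binding protein gene cbpG, from 17.8 ± 1.81 to 56.3 ± 8.77 and 79.6 ± 5.36. The falls of cprF and DDB_G0284277 were shared as well. The retrotransposon gene DDB_G0291223_RTE fell from 54.4 ± 1.96 CPM to 1.499 ± 0.411 and 0.686 ± 0.139 (log2 fold changes -5.17 ± 0.108 and -6.28 ± 0.124, edgeR adjusted p = 3.07e-14 and 5.45e-15), and of the 10 leading genes lower in both mutants, 7 were annotated as retrotransposon genes. In all, 1163 genes were higher in both mutants and 1283 lower in both, against 397.8 and 422.2 for independent calls, and 108 had opposite directions. At least 2-fold changes in both were found for 154 higher and 95 lower genes. Both mutants were compared with the same WT libraries, which alone can make calls coincide. All 12 libraries, WT included, were then simulated without changes from the WT means and the fitted spread. In 20 such simulations, 0 genes were shared in either direction by edgeR. At an unadjusted p under 0.05 a mean of 51.65 higher and 47.5 lower genes were shared, where the data gave 1471 and 1538. As the real WT libraries were not kept, departures of single WT libraries are not covered by these simulations. With 2 of the real WT libraries given to each mutant, in all 6 ways, 784 to 836 genes were higher in both and 873 to 1046 lower, against 220.9 to 300.2 and 244.9 to 309.3 for independent calls. Across genes, which are not independent replicates, the log2 fold changes of both mutants correlated with r = 0.702, where the simulated mutants gave a mean r of 0.509. The covariance was 0.1973, which exceeded the simulated mean of 0.01037 by 0.187. With split WT libraries, r was 0.512 to 0.7005 and the covariance 0.1646 to 0.2032.

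Transposable element genes as a group fell in part. Of 154 tested element genes, 46 fell and 15 rose in ttpA-C231S (camera adjusted p = 0.0166, adjusted p = 0.286 with an estimated correlation), and 46 fell and 26 rose in ttpA-E236fsx (camera adjusted p = 0.0579, and 0.0294 and 0.0406 without its replicates 1 and 2), the same counts as when adjusted over the list alone. The list's median log2 fold change was -0.065 and -0.025 and its mean -0.606 and -0.827, with the ttpA-E236fsx median between -0.035 and 0.04 over the scalings. Most of the genes that fell lay in runs of element genes in the reference order, taken over tested genes only. As 154 of 520 element genes were tested, untested genes were passed over. A gene counted as alone may thus lie beside untested element genes. Of 42 element genes in unbroken runs of at least 5, 31 fell in each mutant and 0 and 3 rose, with a median log2 fold change of -2.06 in ttpA-C231S and -2.93 in ttpA-E236fsx. The 2 element genes without counts in ttpA-E236fsx were also set to a floor of 3 counts over its 4 libraries. The median of these 42 genes was then -2.93, which so few genes can hardly move. Of the 42 genes, 30 lie in a single stretch at the start of chromosome 1. In that stretch 26 of 33 tested genes, element genes and others, were lower in both mutants. Neighbouring genes of the same stretch may not be independent. The counts for long runs thus rest mainly on that stretch and do not show that genes in runs fall in general. Of 49 element genes in runs of 2 to 4, 10 fell and 6 rose in ttpA-C231S and 9 fell and 9 rose in ttpA-E236fsx, with medians of -0.035 and 0.025. Of 60 element genes with no tested element gene next to them, 4 fell and 9 rose in ttpA-C231S and 6 fell and 14 rose in ttpA-E236fsx, with medians of 0.207 and 0.202. Reads of repeated elements may match several copies, and how such reads were counted is not given in the sources used here.

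The comparison of ttpA-E236fsx with ttpA-C231S asks where the altered alleles differ. The gap was widest for DDB_G0267896, at 0.456 ± 0.114 CPM (SD, n = 4) in ttpA-C231S and 31.6 ± 5.80 in ttpA-E236fsx (log2 fold change 6.10 ± 0.183, edgeR adjusted p = 5.02e-12). DDB_G0280295_ps was higher by 4.79 ± 0.0971 and DDB_G0268208 by 4.84 ± 0.152 in ttpA-E236fsx, and DDB_G0279951 was lower by -3.31 ± 0.161. DDB_G0279973 stood at 83.5 ± 2.08 CPM in ttpA-C231S, against 20.9 ± 1.503 in WT and 21.3 ± 1.25 in ttpA-E236fsx, a log2 fold change of -1.97 ± 0.0524 between the mutants (adjusted p = 1.11e-12). The Rab GTPase gene rabR was near its floor in ttpA-C231S, at 0.678 ± 0.190 CPM, and varied widely elsewhere, at 34.6 ± 28.9 CPM in WT and 26.8 ± 23.9 in ttpA-E236fsx. Its log2 fold change was -5.71 ± 1.03 in ttpA-C231S against WT (adjusted p = 5.29e-04) and 5.29 ± 1.06 in ttpA-E236fsx against ttpA-C231S (adjusted p = 1.25e-03). The fall was 52.4 times, and 31.9 times without WT replicate 1, and the latter log2 fold change was 4.54 without ttpA-E236fsx replicate 1, both still past the threshold.

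Between the mutants 1848 genes were higher and 1565 lower in ttpA-E236fsx, 34.2% of the tested genes, with 237 and 68 changed at least 2-fold. The balance of directions depends on the scaling here too: 2104 were higher and 1280 lower with library size alone, and 1640 higher and 1717 lower with limma on the deposited normalized values. The libraries of both mutants did not overlap in 33.9% of tested genes, against 2.86% by chance. Of the 1163 genes higher in both mutants, 458 were further from WT in ttpA-E236fsx and 76 in ttpA-C231S, and 629 were not separated. Of the 1283 lower in both, 457 were further from WT in ttpA-E236fsx, 73 in ttpA-C231S and 753 were not separated.

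Several lists that had moved in both mutants were further from WT in ttpA-E236fsx. Protease and lysosomal enzyme genes were lower in 15 of 25 cases and higher in 2 (15 and 3 adjusted over the list alone; camera adjusted p = 5.96e-08, adjusted p = 0.111 with an estimated correlation), with ctsB at -1.19 ± 0.0444 and tpp1F at -1.06 ± 0.051. Prestalk genes were higher in 11 of 17 cases and lower in 0 (12 and 0 adjusted over the list alone; camera adjusted p = 7.38e-05, adjusted p = 0.0949 with an estimated correlation), with cprA at 1.32 ± 0.0826 and tagC at 0.89 ± 0.0656. Ribosomal protein genes were lower in 66 of 79 cases and higher in 1 (69 and 1 adjusted over the list alone; camera adjusted p = 2.09e-19, adjusted p = 0.434 with an estimated correlation). Actin cytoskeleton genes were lower in 26 of 45 cases and higher in 2 (29 and 2 adjusted over the list alone; camera adjusted p = 5.53e-08, adjusted p = 0.434 with an estimated correlation), with corB at -0.56 ± 0.0431. Heat shock and chaperone genes were lower in 15 of 31 cases and higher in 2 (15 and 3 adjusted over the list alone; camera adjusted p = 0.00278, adjusted p = 0.346 with an estimated correlation), with grp94 at -0.73 ± 0.0676. The vacuolar proton pump genes were lower in 6 of 9 cases, also adjusted over the list alone (camera adjusted p = 0.00414, adjusted p = 0.508 with an estimated correlation). Cytochrome P450 genes were higher in 12 of 29 cases and lower in 0, also adjusted over the list alone (camera adjusted p = 0.00217, adjusted p = 0.372 with an estimated correlation), with cyp508A4 at 1.62 ± 0.113.

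Among 25 mitochondrial ribosomal protein genes, 6 were lower in ttpA-E236fsx than in ttpA-C231S and 0 higher, also adjusted over the list alone (camera adjusted p = 0.00104, adjusted p = 0.434 with an estimated correlation), with mrpl27 at -0.31 ± 0.0561 and mrps10 at -0.25 ± 0.0452. Against WT, 1 rose and 0 fell in ttpA-C231S, also adjusted over the list alone (camera adjusted p = 0.563), and 1 rose and 5 fell in ttpA-E236fsx (1 and 4 adjusted over the list alone; camera adjusted p = 0.0579, and 0.0402 and 0.0076 without its replicates 3 and 4), or 2 higher and 3 lower with library size alone. Early development and cAMP signalling genes were higher in ttpA-E236fsx than in ttpA-C231S in 8 of 24 cases and lower in 0, also adjusted over the list alone (camera adjusted p = 0.0293, adjusted p = 0.508 with an estimated correlation). The call was lost without ttpA-C231S replicate 1 or 2 (adjusted p = 0.0507 and 0.0786). The phosphodiesterase gene pde4 was higher by 0.84 ± 0.119 and pdiA, for the phosphodiesterase inhibitor, by 0.65 ± 0.102. Of 32 DNA replication and cell cycle genes, 2 were lower and 0 higher, also adjusted over the list alone, namely cycA (-0.47 ± 0.0577) and mcm4 (-0.34 ± 0.0882), with a list median of -0.136 and with 2 higher and 2 lower by library size alone (camera adjusted p = 0.0293, adjusted p = 0.716 with an estimated correlation). That call was lost without ttpA-E236fsx replicate 1 or 4 (adjusted p = 0.242 and 0.0523).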

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

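No test in this part was chosen after a result was seen. For each named gene and genotype, the gap between the highest or lowest library and its nearest neighbour was divided by the range of the 4 libraries, and values are given where this ratio passed Dixon's critical value. That held in 23 of 411 groups, where chance gives about 1 in 20, and in 0 of 18 groups of library measures (totals, factors and component scores). By library the genes numbered 6 in ttpA-E236fsx 1, 5 in WT 1, 4 in ttpA-C231S 3, 3 in ttpA-E236fsx 4, 2 in ttpA-C231S 4, and 1 each in ttpA-C231S 2, ttpA-E236fsx 3 and WT 2.

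Among WT libraries, WT 1 stood low for sodC at 946 CPM (the other libraries 1034 to 1041), for DD3-3 at 2173 CPM (2392 to 2422) and for cf45-1 at 377 CPM (414 to 422). The same library stood high for dnaja1 at 10.7 CPM (7.91 to 8.32) and for DDB_G0281345 at 3.48 CPM (2.61 to 2.72). In WT 2, DDB_G0270330 was low at 1.25 CPM (1.83 to 1.95).

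In ttpA-C231S 3, values stood high for csaA at 12.6 CPM (9.73 to 10.1), proA at 1123 CPM (1059 to 1068), DDB_G0267328_RTE at 1.88 CPM (0.809 to 0.949) and DDB_G0290839 at 0.718 CPM (0.529 to 0.539). ttpA-C231S 4 was high for abcG21 at 25.5 CPM (16.6 to 18.1) and for vatC at 239 CPM (218 to 221), and ttpA-C231S 2 was low for tagC at 16.3 CPM (19.0 to 19.1).

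In ttpA-E236fsx 1, values stood high for sibE at 173 CPM (124 to 126), ctsB at 187 CPM (173 to 175), pks14 at 7.24 CPM (5.85 to 5.94), expl2 at 5.72 CPM (4.88 to 5.02) and DDB_G0289205 at 3.52 CPM (1.66 to 1.89), and low for DDB_G0271152 at 15.1 CPM (19.6 to 20.5). ttpA-E236fsx 4 was high for cyp508A4 at 153 CPM (all others 148 when rounded) and for H2Bv3 at 177 CPM (all others 164 when rounded), and low for hdaC_ps5 at 4.32 CPM (4.99 to 5.10). ttpA-E236fsx 3 was low for DDB_G0267210_RTE at 0.943 CPM (1.34 to 1.37).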

How the results depend on the processing

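No alternative in this part was chosen after the result was seen. The total numbers of genes higher and lower, per comparison and in both mutants, stayed within 1.5 times their values under each alternative run. These were other scalings, no filter, DESeq2, limma, compared groups alone and the replicate block. Some counts of list members moved further with library size alone, and counts of 2-fold changes were not run under the alternatives. Leaving out each library in turn gave 1314 to 1562 genes higher and 1508 to 1693 lower in ttpA-C231S than WT, and 2226 to 2487 and 2124 to 2308 for ttpA-E236fsx against WT. Between the mutants the ranges were 1513 to 1833 higher and 1321 to 1579 lower, and for both mutants 974 to 1202 higher and 1111 to 1316 lower. The number of gene lists called ran from 9 to 11, 8 to 11 and 9 to 10 in the comparisons of ttpA-C231S with WT, ttpA-E236fsx with WT, and the mutants.

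With an estimated correlation camera called 0 lists in each comparison, against 11, 8 and 10 with the preset one, with lowest adjusted p of 0.172, 0.104 and 0.0949 and 2, 4 and 3 lists at an unadjusted p under 0.05. The estimated correlation, up to 0.663 for the vacuolar proton pump, widens the error of a list's mean. Fry, which asks whether a list moves on balance rather than against other genes, called 16, 23 and 13 lists.

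The replicate number as a block gave 1636 genes higher and 1795 lower for ttpA-C231S, 2512 and 2348 for ttpA-E236fsx, 1835 and 1596 between the mutants, and 1189 and 1296 in both mutants. Of 411 tests of named genes, library size alone ended 9 calls and added 8, DESeq2 ended 7 and added 5, limma ended 5 and added 5, the block ended 2 and added 8, DESeq2 size factors in edgeR ended 2, and no filter ended 2. The compared groups alone ended 3 and added 4 of 407. Leaving out single libraries ended 80 and added 26 of 3288, and for lists ended 14 and added 12 of 624. No result changed direction while called. The planned motif windows, ttpA level and ttpA-Y242fsx alternatives were not run. In simulations with 4 libraries per group at this depth and spread, small differences were missed in part: of 1.5-fold changes, 70.4% were called for ttpA-E236fsx and 79% for ttpA-C231S. Far fewer genes were changed there than were called in the data, which makes the adjusted threshold stricter. Recovery in the data may therefore differ.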

Other observations

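The tests that weigh an explanation and the counts over other splits of the libraries were chosen after the results were seen, while the gene lists were not. Other gene lists had mixed directions. Of 24 early development and cAMP signalling genes, 12 rose and 5 fell in ttpA-E236fsx (12 and 6 adjusted over the list alone; camera adjusted p = 0.179), with the phosphodiesterase gene pde4 up by 2.16 ± 0.138 and the adhesion gene csaA by 0.71 ± 0.0939 on the log2 scale. In ttpA-C231S 5 rose and 3 fell, also adjusted over the list alone (adjusted p = 0.917), and the list's median of 0.001 there changed sign between scalings (-0.001 to 0.043). Of 14 pre-starvation genes, 8 rose and 4 fell in ttpA-E236fsx and 5 and 3 in ttpA-C231S (8 and 4, and 6 and 3, adjusted over the list alone; adjusted p = 0.76 and 0.651). The counting factor gene cf45-1 fell by 1.73 and 1.04 in ttpA-E236fsx and ttpA-C231S, while cprA rose by 2.69 and 1.37. The camera direction of that list was up, as were its median and mean, and that of fry was down. Prespore genes rose in 4 of 12 cases in each mutant, with 1 and 0 lower in ttpA-C231S and ttpA-E236fsx (4 and 2, and 3 and 0, adjusted over the list alone; adjusted p = 0.392 and 0.167), at a median level of 3.01 CPM. Of 20 oxidative stress genes, 5 rose and 3 fell in ttpA-C231S and 10 and 3 in ttpA-E236fsx (7 and 3, and 10 and 3, adjusted over the list alone; adjusted p = 0.102 and 0.0673, the latter 0.0448 without ttpA-E236fsx replicate 1). Beside sodC, the NADPH oxidase gene noxA rose by 0.67 ± 0.0428 and 0.84 ± 0.0429. Of 13 glycolysis genes, 6 fell and 1 rose in ttpA-C231S and 8 and 1 in ttpA-E236fsx (7 and 2, and 8 and 1, adjusted over the list alone; adjusted p = 0.0702 for each, and 0.0463 and 0.0447 without WT replicate 4), with the phosphofructokinase gene pfkA at -0.45 ± 0.0535 and -0.44 ± 0.0535.

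Among 62 ABC transporter genes, 21 rose and 13 fell in ttpA-C231S and 27 and 12 in ttpA-E236fsx (21 and 13, and 27 and 13, adjusted over the list alone; adjusted p = 0.187 and 0.124). Of 27 macropinocytosis and Ras signalling genes, 6 fell and 2 rose in ttpA-C231S and 15 and 5 in ttpA-E236fsx (6 and 2, and 16 and 5, adjusted over the list alone; adjusted p = 0.129 and 0.0603, the latter 0.0463 without WT replicate 1). The vacuolin gene vacB rose by 1.04 ± 0.0989 in ttpA-E236fsx and pkbA fell by 0.30 and 0.35 in ttpA-C231S and ttpA-E236fsx, and the list's ttpA-C231S median lay between -0.031 and 0.013 over the scalings. The excess of falls in ttpA-E236fsx depended on the scaling, with 7 lower and 7 higher by library size alone. Cell adhesion genes rose in 4 and 5 of 17 cases and fell in 2 and 5 (5 and 5, and 2 and 5, adjusted over the list alone; adjusted p = 0.671 and 0.903), with sibE down by 0.75 and 1.36. In ttpA-C231S that list's median was -0.003 (-0.005 to 0.039 over the scalings), its mean 0.181 and its camera direction up. Of 23 calcium-binding genes, 8 rose and 7 fell in ttpA-C231S and 10 and 10 in ttpA-E236fsx (9 and 8, and 10 and 10, adjusted over the list alone; adjusted p = 0.651 and 0.781), with pefA up by 1.48 ± 0.0591 in ttpA-E236fsx. Their medians of -0.002 (-0.005 to 0.041) and -0.104 stood against means of 0.312 and 0.422 and an upward camera direction. Of 12 metal ion transport genes, 3 rose and 3 fell in ttpA-C231S and 2 and 5 in ttpA-E236fsx, by either adjustment (adjusted p = 0.972 and 0.686), the phagosomal iron transporter gene nramp1 by 0.49 ± 0.0364 in ttpA-C231S. The median and mean in ttpA-C231S were -0.061 and -0.073 with a camera direction of up, and the ttpA-E236fsx median lay between -0.054 and 0.022 over the scalings. Of 11 histone genes, 2 rose and 0 fell in ttpA-C231S and 4 and 2 in ttpA-E236fsx (2 and 0, and 4 and 3, adjusted over the list alone; adjusted p = 0.903 and 0.273), with a ttpA-C231S median of -0.041 (-0.043 to 0.001 over the scalings) and mean of 0.003. Of the tested pseudogenes, 27 rose, 14 fell and 195 were not called in ttpA-C231S, and 52 rose and 15 fell in ttpA-E236fsx (20 and 8, and 44 and 14, adjusted over the list alone; adjusted p = 0.354 and 0.0632, the latter 0.0485 without WT replicate 1). Of 7 cellulose synthesis, expansin-like and sigN genes, 2 rose and 1 fell in ttpA-C231S and 1 and 2 in ttpA-E236fsx, by either adjustment (adjusted p = 0.64 and 0.903), the latter with a median of 0.148, a mean of 0.077 and a camera direction of down. DDB_G0290839 and rabR varied between libraries: they stood at 17.6 and 73.8 CPM in WT 1, 1.17 and 4.38 in WT 4, 27.0 and 58.6 in ttpA-E236fsx 1, and between 0.529 and 0.718 and between 0.405 and 0.846 in ttpA-C231S. For DDB_G0290839 the log2 fold change of ttpA-C231S against WT was -3.77 ± 0.907 (adjusted p = 4.66e-03, and -2.86 without WT replicate 1), and that of ttpA-E236fsx against WT 0.64 (adjusted p = 3.91e-01, and 1.55 with 3.61e-02 without WT replicate 1).

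Between the mutants, further lists were not called by camera. Higher and lower members in ttpA-E236fsx than in ttpA-C231S numbered 1 and 6 for mRNA decay (adjusted p = 0.0935; 1 and 2 with library size alone), 2 and 7 for polyketide synthases (0.0837), both also adjusted over the list alone, and 6 and 11 for the tricarboxylic acid cycle (6 and 13 adjusted over the list alone; 0.308). They numbered 16 and 20 for transposable elements (15 and 17 adjusted over the list alone; 0.431), 19 and 13 for ABC transporters (20 and 14; 0.431), 34 and 12 for pseudogenes (29 and 10; 0.202), 5 and 5 for pre-starvation (6 and 5; 0.732), 7 and 7 for calcium binding (8 and 7; 0.732), 4 and 0 for oxidative stress (2 and 0; 0.49) and 2 and 1 for prespore genes (1 and 1; 0.49). By either adjustment they numbered 4 and 0 for histones (0.206), 4 and 4 for macropinocytosis (0.431), 3 and 3 for cell adhesion (0.933), 3 and 4 for glycolysis (0.732), 1 and 2 for metal ion transport (0.597) and 1 and 2 for cellulose synthesis (0.49). Camera directions were down while median and mean were up for pre-starvation (0.057 and 0.119) and glycolysis (0.024 and 0.009). Median and mean differed in sign for macropinocytosis (-0.039 and 0.011), the tricarboxylic acid cycle (-0.072 and 0.016), cell adhesion (0.009, from 0 to 0.036 over the scalings, and -0.115), metal ion transport (0.060 and -0.016) and cellulose synthesis (0.023 and -0.156), with a downward camera direction in each. Library size alone gave 5 higher and 3 lower for cell adhesion here. Against WT it changed further counts of higher and lower members: in ttpA-E236fsx to 13 and 3 for early development, 7 and 1 for histones, 10 and 6 for calcium binding, 3 and 2 for metal ion transport and 1 and 0 for cellulose synthesis, and in ttpA-C231S to 2 and 4 for glycolysis and 8 and 4 for calcium binding.

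The fall of neighbouring retrotransposon genes in both mutants has several candidate explanations. A lower level of all such transcripts is argued against by the 60 element genes with no tested element neighbour, whose median in ttpA-E236fsx was 0.202 (quartiles -0.104 and 0.672). Loss of one unbroken stretch of chromosome is argued against by 7 of 33 genes in the leading stretch that were not lower in both. Of these, DDB_G0267252 was higher by 0.90 and 0.96, and DDB_G0267254_ps was higher too from 0.0195 CPM in WT. Genes outside the element list also fell: DDB_G0267226 in that stretch (-2.80 and -3.53) and DDB_G0291209_ps at the start of chromosome 6 (-5.84 and -6.85, the latter from 3 counts). These named genes were all chosen after their values were seen. Loss of shorter pieces therefore stays open. The gene order is that of the AX4 reference, and reads of element genes may come from copies elsewhere. Reads moving to other counted copies is argued against in ttpA-C231S, where the 40 genes lower in both lost 208 CPM in sum. The other 114 element genes summed to 810 CPM (SD 19) in WT and 772 CPM (SD 56.9) in ttpA-C231S, a change of -38. In ttpA-E236fsx 218 CPM were lost and the others gained 104, so this explanation stays open in part there. A difference between the cell lines that arose apart from ttpA, which may include several separate losses, cannot be told apart from an effect of ttpA on these 40 genes, as each genotype may be a single line, and the handling of reads that match several copies stays open.

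Of 25 protease and lysosomal genes 11 fell in both mutants, 10 of them further in ttpA-E236fsx, and of 17 prestalk genes 11 rose in both, 8 of them further, while other members moved the opposite way (list adjusted p with an estimated correlation 0.286 and 0.209 for the former, 0.172 and 0.104 for the latter, in ttpA-C231S and ttpA-E236fsx). The scaling of the libraries is argued against as the whole cause, since 28 of the 30 ttpA-E236fsx calls stood under all 3 scalings (alyB and tpp1E did not). Mutant cultures nearer to starvation could raise developmental genes, but the median of the early development list, 0.099 in ttpA-E236fsx, leaves this open, as its members went both ways. In ttpA-E236fsx srfA (1.09) and pde4 (2.16) rose while mybB fell by 0.45, and in ttpA-C231S acaA fell by 0.30 (srfA, mybB and acaA were chosen after their values were seen). The nutritional state of the cultures and an effect of the ttpA alleles therefore cannot be told apart for these genes.

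Ribosomal protein genes fell in 70 of 79 cases in ttpA-C231S and in 75 in ttpA-E236fsx (list adjusted p = 0.341 and 0.286 with an estimated correlation). A bias with coding length or expression level is argued against: over 10000 lists matched on both, the lowest median log2 fold change was -0.119 in ttpA-C231S and -0.268 in ttpA-E236fsx, and 0 were as low as -0.193 and -0.36. The match was imperfect, with a median coding length of 528 against 456 and a median level of 1505 against 2099 CPM, and between the mutants 24 of the 10000 lists were as low. Scaling is argued against by the 72 of 79 genes still lower in ttpA-E236fsx with library size alone. A lower level of these transcripts in the mutants is thus a hypothesis that may be biological, with growth rate untested and with an estimated correlation of 0.605 between the genes, which are not independent.

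Other splits of the same libraries into groups of 4 and 4 gave 0 genes at the edgeR threshold in each comparison. Such splits mix the genotypes, which widens the spread within their groups, so counts at an unadjusted p under 0.05 are given for the real and the highest other split as well. In fits of the compared groups, the real split gave the most genes in each comparison. For ttpA-C231S against WT these were 3381 genes (1 of 35 splits as large, highest other 0, unadjusted 4272 against 1134). For ttpA-E236fsx against WT they were 4510 (1 of 35, highest other 0, unadjusted 5214 against 1412). Between the mutants they were 3399 (1 of 35, highest other 0, unadjusted 4342 against 1202). A rank of 1 of 35 is the best these splits can give, and the libraries of a group may not be separate cultures. Chance is therefore made less likely for these counts but is not excluded. For genes called in both mutants, 1 of 100 splits gave as many as the 1163 higher or the 1283 lower genes, and the highest other was 0 for each (unadjusted 1471 against 496, and 1538 against 409). For the number of gene lists called by camera, other splits gave as many, so chance stays open. These fits held the compared groups alone, adjusted over the 26 lists of 1 comparison, and the real ttpA-E236fsx split gave 9 lists there, against 8 in the main fit. At least 11 lists came from 3 of 35 splits for ttpA-C231S against WT (highest other 12). At least 9 came from 14 of 35 for ttpA-E236fsx against WT (highest other 13), and at least 10 from 3 of 35 between the mutants (highest other 11).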
